A study of Mus musculus with 196 samples.

How the data were processed

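Gene expression was measured on mouse gene arrays in 196 skin samples from 100 untreated mice aged 8 weeks, with 1 ug of total RNA labelled per array. The mice came from a backcross in which females from a cross of FVB/N females with Mus spretus males were mated to FVB/N males. Dorsal skin was labelled as non-anagen in 85 arrays and as anagen, the growth phase of the hair cycle, in 14 arrays, and 97 arrays held tail skin. The sexes were 41 females and 44 males in non-anagen dorsal skin, 8 females and 6 males in anagen dorsal skin, and 48 females and 49 males in tail skin. Both tissues were measured in 96 mice, of which 82 had non-anagen and 14 had anagen dorsal skin.

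The deposited values are log2 expression values from RMA (robust multi-array average: background correction, quantile normalization and summary of probes), and the version of RMA and any further adjustment are not given in the sources used here. Dorsal arrays fell into batches 1 (89 arrays) and 2 (10 arrays), and tail arrays into batches 3 (3 arrays) and 4 (94 arrays), so batch and tissue cannot be told apart. All anagen arrays were in batch 1.

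The table held 35556 probe sets. Of these, 21218 named 1 gene, 1881 named several genes and 12457 named none, and only those naming 1 gene were used. For the 1386 genes with several probe sets, the probe set with the highest mean over all arrays was kept, which left 18820 genes. No filter on low values was applied, and no arrays were left out. No 2 arrays were identical. The number of arrays limits the precision.

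Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with sex as a covariate and, except between tail and dorsal skin, batch within tissue, and p-values were adjusted by the Benjamini-Hochberg method over all 18820 genes. A gene was called at an adjusted p under 0.05. For the tail and dorsal comparison, the anagen comparison and the difference between the anagen effects, a change of at least 2 times (1 on the log2 scale) was also required. The differences between anagen effects and between sex effects were interaction contrasts. For the anagen effects, tails were assigned the hair cycle state of their mouse's dorsal skin. Correlations and permutations were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

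Lists of genes were fixed before the data were examined: posterior Hox genes, anterior and central Hox genes, epidermal differentiation, keratinocyte stress and hyperproliferation, hair shaft keratins, inner root sheath, hair matrix and shaft regulators, hair follicle stem cell, dermal papilla, mitotic cell cycle, pigment synthesis, sebaceous gland, white adipocyte, brown adipocyte, skeletal muscle, cartilage, bone and tendon, dermal extracellular matrix, Schwann cell and myelin, endothelium, smooth muscle, T cell, macrophage and dendritic cell, mast cell, B cell, neutrophil, blood, interferon response, inflammatory cytokines and chemokines, immediate early genes, circadian clock, cholesterol synthesis, Y-linked genes, and X genes expressed from both copies. The last of these lists also held Xist, which comes from the inactive X chromosome and not from both copies. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 33 lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were alternatives.

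The genes named were also set by a rule fixed before the data were examined. It took the 10 largest called differences in each direction for the tail and anagen comparisons and the 5 largest for the others, among annotated genes whose mean in the higher group exceeded the median of all gene means (6.49). It added the 4 members of each list with the largest differences in the tail and anagen comparisons, and Lgr5, Lgr6, Krt15, Tyr, Xist and Eif2s3y. Ddx3y was not analysed here.

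The mouse number pairs the tissues. As a check of this pairing, the deviations of a mouse's tail array from the tail mean were correlated with those of its own dorsal array over all genes. The median correlation in 82 mice was 0.164, against 0 for dorsal arrays of other mice, and 22 tails correlated best with their own mouse's dorsal array. Mouse as a random block and the difference within each mouse were alternatives.

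For the correlation between tissues, each gene was adjusted for sex and batch within each tissue and Pearson's r was taken over the 82 mice with non-anagen dorsal skin, against 100 random pairings of mice. P-values of named genes and of list means came from 100000 permutations, two-sided. The adjusted p-values of genes came instead from the 100 random pairings pooled over all genes, so they are not adjustments of the permutation p-values beside them. A gene was treated as clustered where its values split into groups at least 4 pooled SDs apart with at least 6 mice each, a separation that 0 of 1000 sets of normal values reached. Co-expression was the mean pairwise r among the members of a list, and its difference between tissues was tested by swapping the tissues of mice at random 1000 times. For the scaling of the arrays, 1000 random lists were drawn in which each gene was replaced by 1 of the 100 genes nearest in mean level, a test chosen after seeing the data.

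Alternatives were quantile normalization over all arrays, a shift of arrays to the same median, the mean of all probe sets of a gene, only genes above the median level, a trend and robust fit, other covariates, single batches, and a lower size limit of 1.5 times. Others were chosen after seeing the data: leaving out the 5 arrays least like their group (over 3 interquartile ranges below the lower quartile in mean correlation), leaving out 3 tail arrays with unusual sex-linked values, and adding the mean of the skeletal muscle list as a covariate.

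Each script was tested on simulated data. With 200 of 18820 genes changed, a simulated difference of 0.6 was recovered, at an adjusted p under 0.05 and any size, for 98% of genes in the tail and dorsal comparison, 92% in the anagen comparison, 88% in the difference between anagen effects and 96% for the sexes in dorsal skin, with 3, 12, 5 and 11 false calls. In the comparison of tails by the state of the dorsal skin, 74% of genes were recovered at 0.3. For the correlation between tissues, 5000 genes were simulated, and all 50 with alleles 4 SDs apart were recovered but only 50% of those 2 SDs apart, with 0 false genes, so genes with smaller allele effects are often missed at this limit. In these simulations the genes varied independently, while real genes vary together. The false counts therefore need not hold for the data.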

Results

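Skin from 100 backcross mice was profiled on 196 arrays: 85 of non-anagen dorsal skin, 14 of anagen dorsal skin and 97 of tail skin. Values are log2 expression, and differences are log2 differences with the limma adjusted p over 18820 genes.

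Transcripts of hair shaft and inner root sheath genes were high in tail skin and near the low end of the scale in non-anagen dorsal skin. The mean of the shaft keratins was 10.06 in tail and 7.51 in anagen dorsal skin, and that of the inner root sheath 8.63 and 8.69. Whether all of these transcripts came from growing hair in tail skin was not tested. All 10 hair shaft keratins were called higher in tail skin, with a median difference of 4.42 (camera adjusted p = 2.97e-09, and adjusted p = 0.0557 with an estimated correlation). Krt84 was at 13.04 ± 0.08 (SD, n = 97) in tail skin and 4.87 ± 0.54 (SD, n = 85) in dorsal skin, a difference of 8.17 (adjusted p = 1.55e-189). Dorsal values at this level may be near the background of the arrays. In dorsal batch 1 females the Y-linked genes Kdm5d, Eif2s3y and Uty read 4.72, 3.62 and 3.46, so background differs between probe sets. The sizes and the ranking of such differences can therefore also depend on the background. Krt36 was higher by 7.67, Krt33a by 5.43 and Krt31 by 5.12. Krt84 and Krt36 were not among the 4 shaft keratins with the largest differences between anagen and non-anagen dorsal skin. Across tails Krt84 varied less (SD 0.08) than the mean of the list (SD 0.82, n = 97). The tail levels of Krt84 and Krt36 therefore need not come from growing hair. Keratin-associated proteins, which fill the matrix of the hair shaft, were among the largest differences, with Krtap13 at 7.84, Krtap6-1 at 7.57, Krtap7-1 at 7.29, Krtap8-1 at 7.22, Krtap15 at 6.71 and Krtap21-1 at 6.63. Of the 11 inner root sheath genes, which form the sheath around the growing shaft, 9 were called higher, including Krt25 (5.78), Krt71 (5.72), Krt27 (4.37) and Krt73 (4.30; for the list, adjusted p = 0.278 with an estimated correlation). Hair matrix and shaft regulators had 6 of 16 called higher, with Prr9 at 4.67, the transcription factors Foxn1 at 2.44, Hoxc13 at 2.36 and Dlx3 at 1.80 (for the list, adjusted p = 0.275 with an estimated correlation).

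Pigment synthesis and cell division were higher in tail skin as well. Of 13 pigment synthesis genes 10 were called higher, among them Tyrp1 (3.64), Slc24a5 (2.87), Tyr (2.77, the tyrosinase that starts melanin synthesis) and Pmel (2.61; for the list, adjusted p = 0.112 with an estimated correlation). The mitotic cell cycle list had 4 of 21 members called higher (Bub1 1.49, Aurkb 1.31, Kif11 1.12 and Birc5 1.01). At an adjusted p under 0.05 and any size, where 8243 of all 18820 genes were higher and 8195 lower, all 21 were higher (for the list, adjusted p = 0.289 with an estimated correlation). Hair follicle stem cell genes moved the other way, with 4 of 16 called lower: Fgf18 (-1.78), Krt15 (-1.499), Lhx2 (-1.23) and Lgr6 (-1.03; for the list, adjusted p = 0.342 with an estimated correlation). Lgr5, a stem cell receptor, differed by -0.90 (adjusted p = 1.8e-21), short of the size limit.

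Position along the body was visible in the Hox genes. Of 15 posterior Hox genes 9 were called higher in tail skin, with Hoxd11 at 4.51, Hoxc12 at 3.65, Hoxd10 at 2.93 and Hoxa9 at 2.69 (camera adjusted p = 4.6e-06, and adjusted p = 0.0557 with an estimated correlation). Anterior and central Hox genes had 4 of 21 called lower and 1 higher, with Hoxc8 at -2.72, Hoxa5 at -1.77 and Hoxc6 at -1.67 against Hoxd8 at 1.73 (camera adjusted p = 1.02e-06, and adjusted p = 0.0912 with an estimated correlation).

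Epidermal differentiation genes went both ways between tail and dorsal skin. In this list 5 of 19 genes were called higher and 2 lower, and at any size 13 were higher and 5 lower. Krt2, a keratin of the upper epidermis, was higher by 7.59, Sprr1b by 4.48 and Tgm3 by 3.76, while Krt77, another epidermal keratin, was at -6.01 (for the list, camera adjusted p = 0.0229, and adjusted p = 0.419 with an estimated correlation). Keratinocyte stress and hyperproliferation genes had 9 of 14 called higher, with Sprr2d at 4.64, Stfa3 at 3.96, Il1f6 at 3.66 and Stfa1 at 3.30 (for the list, adjusted p = 0.278 with an estimated correlation). Sprr2b, a cornified envelope gene, was higher by 6.51.

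**Figure D1:**
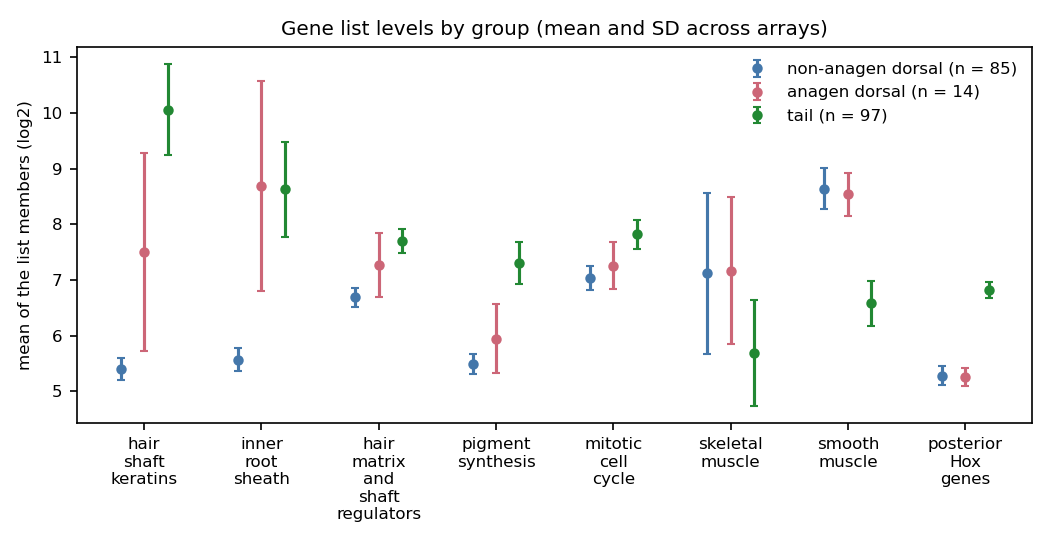
Mean of the members of 8 gene lists (log2) in non-anagen dorsal, anagen dorsal and tail skin, with points at the mean and bars at the SD across 85, 14 and 97 arrays. Hair shaft and inner root sheath genes are high in tail skin and spread widely in anagen dorsal skin.

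Muscle was lower in tail skin. Of 10 smooth muscle genes 9 were called lower, with Des at -3.50, Myh11 at -3.25, Cnn1 at -3.02 and Actg2 at -2.50 (for the list, adjusted p = 0.108 with an estimated correlation). Skeletal muscle had 16 of 22 genes called lower, with Myh4 at -2.97, Ckm at -2.27, Tnnc2 at -2.25 and Tnnt3 at -2.21, and these varied widely between dorsal arrays (Myh4 SD 2.04, n = 85; adjusted p = 0.592 with an estimated correlation). Cartilage, bone and tendon genes had 4 of 15 called higher, led by Chad (3.82), Fmod (2.59), Tnmd (1.96) and Comp (1.43). The dermal extracellular matrix list had 1 of 16 called higher, the collagen cross-linking enzyme Lox (2.26). Its median of 0.11 became -0.03 with arrays shifted to the same median.

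Several immune lists were lower in tail skin, and mast cell genes were higher. Of 10 T cell genes 4 were called lower, with the T cell receptor components Cd3g at -3.74 and Cd3e at -2.55, Itgae at -1.21 and Cd2 at -1.21 (for the list, adjusted p = 0.0557 with an estimated correlation). Interferon response had 4 of 16 lower (Usp18 -2.74, Gbp2 -1.502, Ifit1 -1.07 and Oasl2 -1.002; adjusted p = 0.321 with an estimated correlation), and inflammatory cytokines and chemokines had 3 of 21 lower (Cxcl9 -2.14, Ccl8 -1.32 and Cxcl10 -1.05; adjusted p = 0.342 with an estimated correlation). Macrophage and dendritic cell genes went both ways, with 4 of 15 lower and 1 higher. The 4 were the Langerhans cell marker Cd207 (-1.70) and the antigen presentation genes H2-Ab1 (-1.62), Cd74 (-1.51) and H2-Aa (-1.48), while the median of the list was 0.54, its mean -0.09 and the direction of camera lower (adjusted p = 0.418). Mast cell genes had 4 of 10 called higher, namely Tpsab1 (1.92), Tpsb2 (1.39), Cpa3 (1.15) and Mcpt4 (1.005; for the list, adjusted p = 0.372 with an estimated correlation).

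In the remaining lists few members were called. Neutrophil genes had 1 of 8 higher (Cxcr2 1.90) and 1 lower (Mpo -1.44), and sebaceous gland genes had 1 of 14 higher (Elovl3 1.28) and 2 lower (Awat2 -1.66 and Scd3 -1.18). Dermal papilla genes had 3 of 14 higher (Vcan 1.51, Hhip 1.201 and Wif1 1.07), with a median of -0.08 and a mean of 0.07, and brown adipocyte genes had 2 of 10 lower (Slc27a2 -1.60 and Ppargc1a -1.33). A single member was higher in endothelium (Lyve1 1.67 among 12), immediate early genes (Fosb 1.17 among 15), circadian clock (Cry1 1.29 among 13) and cholesterol synthesis (Idi1 1.18 among 12). None was called among 17 white adipocyte, 7 Schwann cell and myelin, 8 B cell, 2 blood, 3 Y-linked and 5 X genes expressed from both copies. Other large decreases in tail skin were Ifitm6 (-5.78), Mrgprb3 (-4.97), Tspan8 (-3.96), Cd7 (-3.67), Clca3a1 (-3.62) and H2-Q6 (-3.43).

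Between tail and non-anagen dorsal skin 742 genes were called higher in tail skin and 381 lower. At an adjusted p under 0.05 and any size, 8243 of 18820 genes were higher and 8195 lower. A count of list members at any size therefore says little without these totals. The counts of called members adjusted over the list alone were equal to those over all genes in each of the 33 lists. Camera passed 19 lists and none of them with an estimated correlation. The mean of the array medians was 5.95 in tail and 5.81 in dorsal skin, and with arrays shifted to the same median the median of all genes moved to -0.137 and the counts to 560 higher and 529 lower, so the split between directions depends on the scaling. Batch and tissue cannot be told apart.

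**Figure D2:**
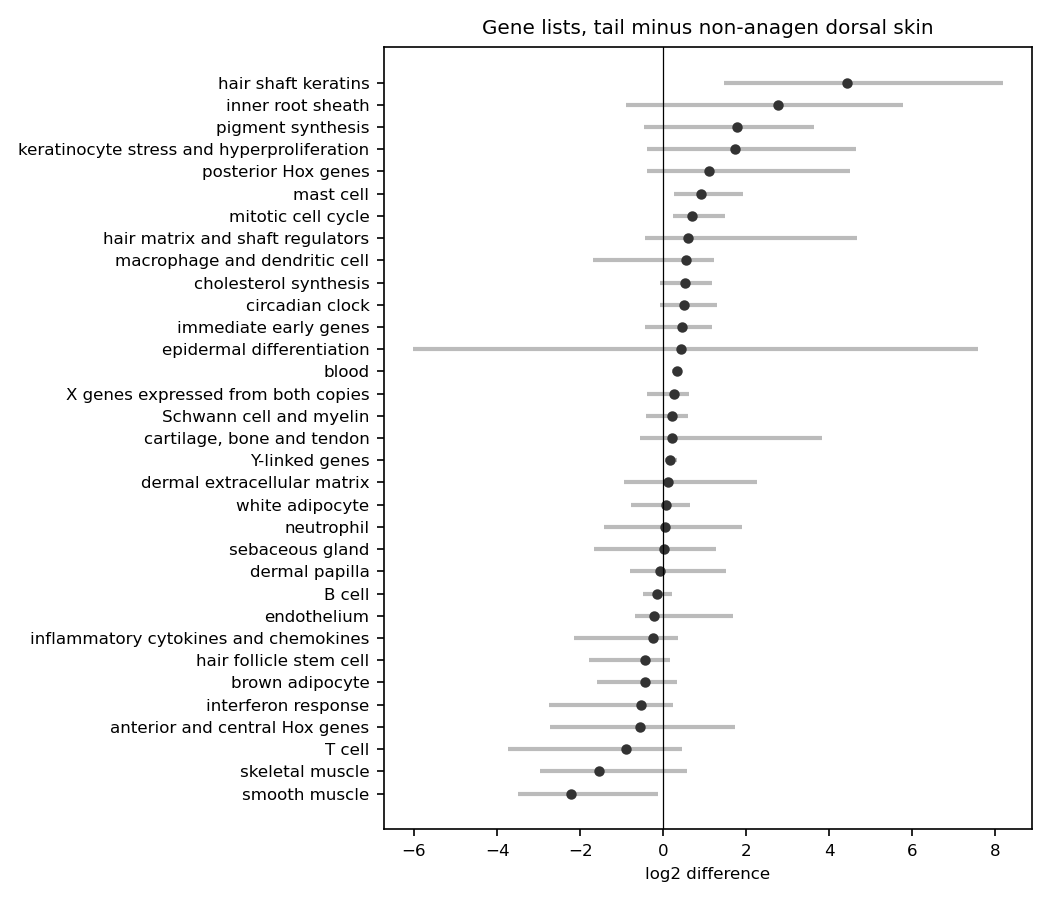
Log2 difference of tail minus non-anagen dorsal skin for the members of each of the 33 gene lists, with points at the median and lines from the lowest to the highest member. The hair shaft keratins have the highest median, 4.42, and smooth muscle the lowest, -2.23.

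The largest increases in anagen over non-anagen dorsal skin were in genes that build hair. Of the 11 inner root sheath genes 9 were called higher, with Krt71 at 4.98 (10.30 ± 2.13, SD, n = 14, against 5.32 ± 0.42, SD, n = 85; adjusted p = 1.91e-32), Krt25 at 4.87, Krt27 at 4.59 and Tchh at 3.95. Hair shaft keratins had 8 of 10 called higher, including Krt33a (4.04), Krt86 (3.46), Krt31 (3.28) and Krt33b (1.90). Keratin-associated proteins led the ranking, with Krtap15 at 5.46, Krtap8-1 at 5.38, Krtap7-1 at 5.08, Krtap19-1 at 4.97, Krtap6-1 at 4.47, Krtap19-3 at 4.34 and Krtap19-5 at 4.33. The mean of the inner root sheath list lay above that of every non-anagen array in 12 of the 14 anagen arrays.

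The regulators of the shaft and the pigment genes moved by smaller amounts. Hair matrix and shaft regulators had 2 of 16 called higher (Prr9 3.41 and Dlx3 1.01), and at any size 10 over all genes and 13 adjusted over the list alone. Pigment synthesis had 1 of 13 called higher (Tyrp1 1.04), and at any size 9 over all genes and 12 adjusted over the list alone, among them Dct (0.69), Pmel (0.66) and Tyr (0.58). In the blood list Slc4a1 rose by 1.11, and in the epidermal list Sprr1b rose by 1.14. The epidermal list as a whole did not rise, with a mean of 10.25 in anagen and 10.27 in non-anagen dorsal skin. These hair, pigment and blood lists, the last with 2 measured members of which only Slc4a1 was called, passed camera also with an estimated correlation (adjusted p = 5.55e-08 for the inner root sheath, 1.14e-05 for the shaft keratins, 0.00467 for the regulators, 0.0093 for pigment and 0.0151 for blood). Mitotic genes had 4 of 21 higher at any size over all genes and 10 adjusted over the list alone, with Aurkb at 0.39 and Plk1 at 0.36 (for the list, adjusted p = 0.257 with an estimated correlation). The stem cell genes Krt15 (-0.24, adjusted p = 0.0652) and Lgr5 (0.14, adjusted p = 0.722) did not pass, and Lgr6 was at -0.44 (adjusted p = 0.0103), short of the size limit.

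In total 128 genes rose in anagen dorsal skin and 1 fell, the ion transporter Slc26a7 (-1.06). At the limit of 2 times, the counts of called members adjusted over the list alone were equal to those over all genes in each list. At any size 774 genes were higher and 676 lower. All anagen arrays were in batch 1, and within that batch the counts were 128 and 1.

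The tail skin of mice with anagen dorsal skin was not separated gene by gene from that of mice with non-anagen dorsal skin. With limma 0 genes passed in 14 against 82 tails, and 796 had an unadjusted p under 0.05. The hair lists leaned in the direction opposite to dorsal skin, with a median of -0.62 for the shaft keratins and -0.59 for the inner root sheath and 0 members called (adjusted p = 0.0655 and 0.0714 with an estimated correlation). Keratinocyte stress genes had a median of 0.34, with 0 of 14 called over all genes and 8 adjusted over the list alone (adjusted p = 0.0655 with an estimated correlation).

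Tail arrays have no hair cycle label, so tails were grouped by the dorsal skin of their mouse and not by their own hair growth. The difference between mice with anagen and with non-anagen dorsal skin was larger in dorsal skin than in tail skin for 145 genes. It was smaller for 0 at the limit of 2 times, and the counts at any size were 459 and 183. Without the 5 arrays least like their group, a choice made after seeing the data, the counts were 154 and 1. Krtap15 differed by 6.15 (SE 0.46), Krtap19-1 by 5.79, Krtap8-1 by 5.66, Krt71 by 5.54 and Krt25 by 5.42. Hair shaft keratins had 9 of 10 called, the inner root sheath 10 of 11 and the hair matrix and shaft regulators 4 of 16, and these 3 lists and the blood list (1 of 2 measured members called) passed camera also with an estimated correlation (adjusted p = 8.26e-07, 2.11e-09, 0.000609 and 0.0055). With mouse as a random block the count was 145.

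In female dorsal skin single enzyme genes had large differences in both directions, and most endothelium genes were lower than in males. Cyp2g1, a cytochrome P450, was at 11.002 ± 1.18 (SD, n = 41) in females and 6.68 ± 1.54 (SD, n = 44) in males, a difference of 4.35 (adjusted p = 1.83e-22). Carns1, which makes carnosine, was higher in females by 2.53, the progesterone-metabolizing enzyme Akr1c18 by 1.48 and Egfl6 by 1.34, while Cyp2b23 (-1.65) and the neutrophil peroxidase Mpo (-1.57) were lower. Of 12 endothelium genes 11 fell in females and 12 when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 1.55e-10, and adjusted p = 0.129 with an estimated correlation). Smooth muscle had 7 of 10 lower (10 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), and the dermal extracellular matrix 9 of 16 lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation).

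Cholesterol synthesis was lower in female dorsal skin, with 8 of 12 genes lower and 1 higher (10 and 1 adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.00228). Sebaceous gland genes had 4 of 14 lower (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), and epidermal differentiation had 7 of 19 higher (12 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). Mast cell genes had 0 of 10 called. Xist, the transcript of the inactive X chromosome, was higher by 6.68, and the Y-linked genes Eif2s3y (-5.64), Uty (-4.82) and Kdm5d (-3.06) were lower. Krt15, Lgr5, Lgr6 and Tyr did not pass.

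In female dorsal skin 1165 genes were higher and 1149 lower, of which 41 and 158 differed by at least 0.5. The split depended on the scaling, with 570 higher and 1803 lower when arrays were shifted to the same median and 1066 and 1572 after quantile normalization. Within batch 1 the counts were 774 and 938.

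In female tail skin Cyp2g1, Carns1 and Akr1c18 were higher as in dorsal skin, and of the lists outside the sex chromosomes cholesterol synthesis and macrophage and dendritic cell genes held with an estimated correlation. Cyp2g1 was higher by 2.97 (8.81 ± 1.16, SD, n = 48, against 5.79 ± 0.94, SD, n = 49; adjusted p = 1.15e-21), the wax synthase Awat2 by 0.84, Carns1 by 0.82 and Akr1c18 by 0.80, and the lipid genes Pctp (-0.67) and Hacl1 (-0.63) were lower. Lgr5 was higher by 0.37 (adjusted p = 0.0335). White adipocyte genes had 7 of 17 higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.0787 with an estimated correlation), and mast cell genes had 4 of 10 higher (7 adjusted over the list alone; adjusted p = 0.0935 with an estimated correlation). Macrophage and dendritic cell genes had 1 of 15 higher (13 adjusted over the list alone) and cholesterol synthesis 5 of 12 lower (8 adjusted over the list alone), with an adjusted p of 0.0485 and 0.032 with an estimated correlation. Skeletal muscle genes had a median of 0.37 and inner root sheath genes 0.42, with 0 of 22 and 0 of 11 called over all genes and 0 and 7 adjusted over the list alone (adjusted p = 0.332 and 0.231 with an estimated correlation).

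The sex-linked genes had the largest sex differences in tail skin, with Xist at 7.01, Eif2s3y at -6.51, Uty at -5.53 and Kdm5d at -3.97. In all 309 genes were higher and 225 lower in females, 42 and 19 of them by at least 0.5. With arrays shifted to the same median the counts were 305 and 399. Within batch 4 they were 294 and 222, and with the mean of the skeletal muscle list as a covariate, chosen after seeing the data, they were 172 and 150. In both tissues, measured in the same mice, 65 genes were higher and 94 lower in females, where 19.1 and 13.7 would be shared if the tissues were independent, and 4 and 10 had the opposite direction in tail skin.

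**Figure D3:**
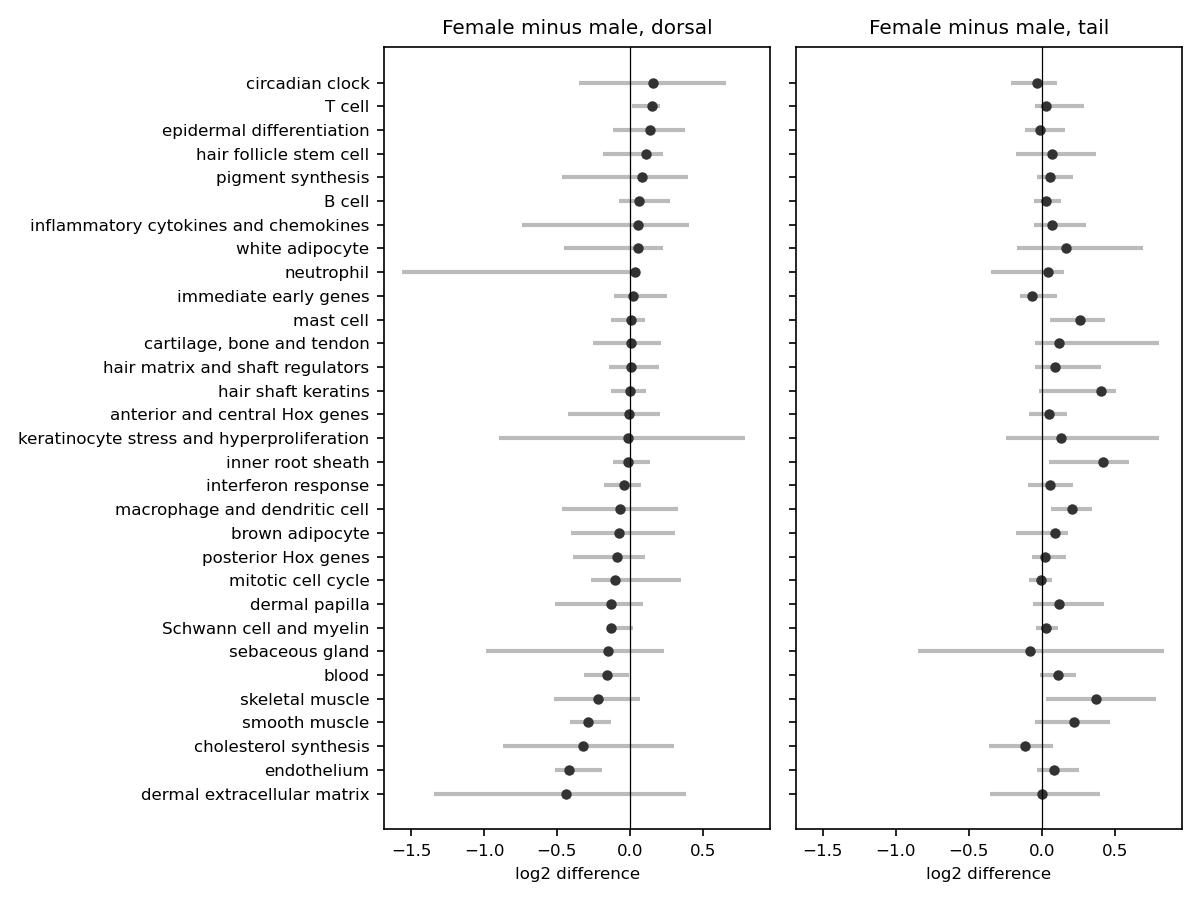
Log2 difference of female minus male for the members of gene lists in non-anagen dorsal skin (left) and tail skin (right), with points at the median and lines from the lowest to the highest member. Endothelium has a median of -0.42 in dorsal and 0.08 in tail skin.

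The sex difference itself differed between the tissues for 1711 genes. The female minus male difference was higher in tail skin for 839 and lower for 872, and 223 and 29 differed by at least 0.5. Endothelium had 11 of 12 members higher (12 adjusted over the list alone; adjusted p = 0.0512 with an estimated correlation), smooth muscle 8 of 10 (10 adjusted over the list alone; adjusted p = 0.0512 with an estimated correlation) and the dermal extracellular matrix 10 of 16 (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). Skeletal muscle had a median of 0.62 with 0 of 22 called over all genes or adjusted over the list alone (adjusted p = 0.404 with an estimated correlation). Cholesterol synthesis had 6 of 12 higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0668 with an estimated correlation). Among named genes Aldh1l2 (1.36), Serpinb6c (1.34), Meg3 (1.34), Lox (1.34) and Cyp2b23 (1.33) were higher, and Carns1 (-1.70), Cyp2g1 (-1.38), Cyp17a1 (-0.80), Gadl1 (-0.76), Hamp2 (-0.67) and Krt15 (-0.29) lower. The count was 2043 with mouse as a random block and 1288 within batches 1 and 4, and the share of higher genes was 49.0%, against 70.0% with arrays shifted to the same median and 60.1% after quantile normalization.

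Dorsal batch 2 differed from batch 1 in 2 genes, both lower and both Y-linked: Eif2s3y (-0.81) and Uty, the latter named after its value was seen. For Eif2s3y much of this came from 3 females, in which the gene is absent and the value is background (1.96 in batch 2 against 3.62 in batch 1), while males were at 8.74 (n = 7) and 9.15 (n = 40, hair cycle stages together). Over all genes, the mean of batch 2 lay closer to that of the other dorsal arrays (0.27 scaled units) than in any of 100 random sets of 10 arrays (lowest 0.327). Whether the dorsal values had been adjusted for batch is not given in the sources used here, and after such an adjustment the count would not measure the original batch difference. With limma 217 genes had an unadjusted p under 0.05 in 10 against 75 arrays. Hair shaft keratins (median 0.13) and inner root sheath genes (median 0.15) leaned higher in batch 2, with 0 members of either called over all genes and 0 and 2 adjusted over the list alone, and both lists held with an estimated correlation (adjusted p = 0.00185 and 0.000321).

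Across the comparisons camera passed 115 of 264 lists, and 21 of them with an estimated correlation: 5 of 11 in the anagen comparison, 4 of 11 in the difference between anagen effects, 3 of 11 for the sexes in dorsal and 4 of 21 in tail skin, 1 of 17 in the difference between sex effects, 4 of 10 between batches, and 0 of 19 and 0 of 15 in the tail and dorsal comparison and the comparison of tails.

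Across the 82 mice with both tissues, 366 genes had an r of at least 0.5 between dorsal and tail skin and 0 had an r of -0.5 or less, while the highest count in 100 random pairings of mice was 1. At an adjusted p under 0.05 from the pooled random pairings, 1657 genes passed, 1646 of them with a positive r. Of the 366 genes, 61 split into separate clusters of mice in at least 1 tissue and 14 in both. The 10 genes ranked highest were all clustered, so no r over all mice is given for them. Cwc22, a splicing factor on chromosome 2, was at 11.05 ± 0.27 (SD) in the dorsal skin of 45 mice and 8.30 ± 0.24 in that of 37, with tail means of 11.07 and 8.65, and 80 of the 82 mice fell on the same side in both tissues. Within these sides r was 0.431 (permutation p = 0.00411) and 0.379 (permutation p = 0.0277). The antigen presentation gene H2-Ea on chromosome 17 had dorsal means of 10.68 in 37 mice and 7.50 in 45, with tail means of 9.34 and 6.31. The others were Plscr4, Retsat, Cr2, H2-Eb1, Avl9, Casp4, Dmac1 and Satl1, with 75 to 81 mice on the same side. Krt15 (r = 0.198, permutation p = 0.075; rho = 0.167, permutation p = 0.133; without the 2 farthest mice r = 0.219; adjusted p = 0.326) did not pass after adjustment over 18820 genes, nor did Lgr5 (r = -0.092, permutation p = 0.415; rho = -0.097, permutation p = 0.385), Lgr6 (r = 0.128, permutation p = 0.251; rho = 0.158, permutation p = 0.156) and Tyr (r = 0.042, permutation p = 0.708; rho = 0.016, permutation p = 0.887). Within dorsal batch 1 and tail batch 4, 385 genes had an r of at least 0.5 in 72 mice.

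**Figure D4:**
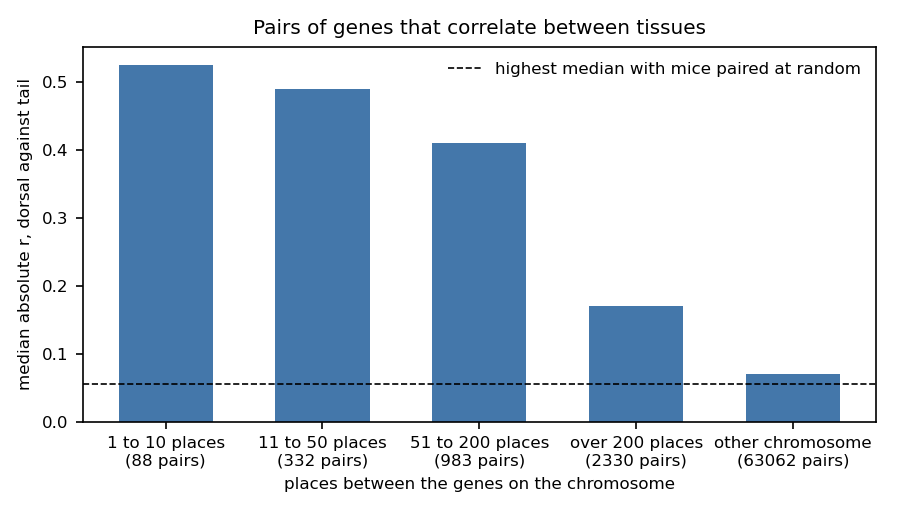
Median absolute r between the dorsal value of 1 gene and the tail value of another (y axis), by the places between them on the chromosome (x axis), among 366 genes that correlated between tissues. The r of each pair was averaged over both directions before the median was taken. The median falls from 0.526 for the nearest pairs to 0.071 for pairs on different chromosomes.

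Several lists of hair, pigment and mitotic genes varied together across mice more in tail skin than in non-anagen dorsal skin. The stem cell list did not differ by this test (0.406 in tail and 0.430 in dorsal skin, adjusted p = 0.72). Dorsal arrays were limited to those labelled non-anagen, while tails were not selected by hair stage. This choice can by itself lower the dorsal r of hair lists. The mean pairwise r of the inner root sheath list was 0.791 in tail and 0.152 in dorsal skin, that of pigment synthesis 0.657 and 0.086, that of the hair shaft keratins 0.496 and 0.104 and that of the mitotic list 0.705 and 0.339. Each difference had a permutation p of 0.001, the smallest that the swaps can give (adjusted p = 0.0046 over 32 lists). Across 97 tails the pigment mean did not follow the inner root sheath mean (r = 0.039, permutation p = 0.71). The lowest tail pigment mean was 5.33, against 7.30 ± 0.38 (SD, n = 97) over all tails, so a single array may add to the pigment r. The rise in tail skin was not particular to hair growth. Skeletal muscle was at 0.847 in tail and 0.692 in dorsal skin (adjusted p = 0.008), and cartilage, bone and tendon at 0.301 and 0.085 (adjusted p = 0.0046). Epidermal differentiation, white adipocyte, T cell, and macrophage and dendritic cell lists were lower in tail skin at an adjusted p under 0.05. In non-anagen dorsal skin the means of the hair shaft keratins (5.40 ± 0.19, SD, n = 85), pigment synthesis (5.49 ± 0.18) and the inner root sheath (5.57 ± 0.20) were below the mean of the array medians (5.81). At low levels noise may lower r. Interferon response genes were the reverse, with 0.077 in tail and 0.414 in dorsal skin (adjusted p = 0.0046), and the same limit applied to their tail value, at a mean of 5.04 ± 0.11 (SD, n = 97) against 5.74 ± 0.40 in dorsal skin. The difference in r of -0.338 depended in part on few mice, with -0.219 without the 2 mice farthest in the list mean and -0.199 with rho. For endothelium the values were 0.650 in tail and 0.661 in dorsal skin (adjusted p = 0.86).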

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

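The tests of the differences between tissues were chosen before the data were examined, and the readings of the splits and all tests of the 3 patterns weighed here were chosen after the results were seen.

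The difference by the state of the dorsal skin itself differed between dorsal and tail skin, by an interaction test, for 145 genes, with Krtap15 at 6.15, Krtap19-1 at 5.79, Krtap8-1 at 5.66, Krt71 at 5.54 and Krt25 at 5.42. Tails were grouped by the dorsal skin of their mouse, so this does not show a response of tail skin to its own hair cycle. Of 100 splits of the mice, 1, the real one, gave 145 genes or more and the highest of the others gave 4, so a chance split is unlikely to give this count.

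The sex difference itself differed between tail and dorsal skin, by an interaction test, for 1711 genes. It was higher in tail skin for Aldh1l2 (1.36), Serpinb6c (1.34), Meg3 (1.34), Lox (1.34) and Cyp2b23 (1.33). It was lower for Carns1 (-1.70), Cyp2g1 (-1.38), Cyp17a1 (-0.80), Gadl1 (-0.76), Hamp2 (-0.67), Krt15 (-0.29) and Eif2s3y (-0.88). Females lack Eif2s3y and their values are background (3.20 in tail skin, 3.62 and 1.96 in dorsal batches 1 and 2). In males it was at 9.90 in tail skin, apart from 3 unusual tail arrays with lower values. In male dorsal skin it was at 9.15 and 8.74 in batches 1 and 2. The value of -0.88 therefore holds a difference between tissues in males together with background in females, and is not a sex effect on expression. Only the real one of 100 splits, 1 of 100, gave 1711 genes or more, and the highest of the others gave 506, so a chance split is unlikely to give this count.

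A chance split is also unlikely to give the counts of the tail and dorsal comparison (1123 genes, highest of the other splits 146), the anagen comparison (129 and 1), and the sexes in dorsal skin (2314 and 2) and in tail skin (534 and 2), each with 1 of 100 splits as large. The splits test the total count and not the single genes. For dorsal batch 2, 4 of 100 splits gave 2 genes or more, and the highest of the others gave 281, several times the real count, which points to a structure of the samples. Because dorsal batch 2 lay unusually close to the other dorsal arrays (0.27 against at least 0.327 in random sets), this does not set batch against other structure. For the tails split by the state of the dorsal skin, the real count was 0, which each of the 100 splits reaches by definition, so the splits do not test chance here. The highest of the others gave 2480 genes, which points to a structure of the tail samples that is not the state of the dorsal skin.

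In 3 male tail arrays Xist was at 7.24, between the other male tails (4.21 ± 0.30, SD, n = 46) and the lowest female tail (10.86), and Eif2s3y lay between the other male tails (9.90) and the female tails (3.20), which speaks against wrong sex labels. Female RNA mixed in at the 4.91% that Xist would need would change Eif2s3y by -0.07, but the change was -2.9. The mean of the 3 arrays lay 0.05 scaled units from that of the other tails over all genes, against at least 0.259 in 100 random sets of 3, and their Xist value lay nearer to the mean of all other tails, female and male together (7.89), than to either sex, so a candidate explanation is a batch adjustment of these arrays made without sex, although the labels place them in batch 4 with other arrays. The dorsal arrays of the same 3 mice had means shifted the same way by less (Xist 6.64, 5.16 to 7.37, against 4.83, 3.80 to 6.78, and Eif2s3y 8.57 against 9.15 in other batch 1 males), with at least 1 array inside the range of the other males, without being centred (0.516, with 69 of 100 random sets as small), which an adjustment of the tail arrays alone leaves open. No biological explanation was tested, and a batch adjustment is not given in the sources used here.

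Among genes whose dorsal and tail values correlated across mice, those near each other correlated with each other. For each pair, the r between the dorsal value of 1 gene and the tail value of the other was averaged over both directions. The median absolute r of pairs up to 10 places apart was 0.526, as inherited alleles shared by both tissues would give. On different chromosomes it was 0.071, against 0.052 to 0.055 with mice paired at random, which speaks against a shared quality or handling of both samples of a mouse as the whole cause. Of the linked pairs with an absolute r of at least 0.5, 38.2% were negative, which speaks against weaker probe binding of the alleles of 1 parent species for all of these genes. Weaker binding for part of the genes stays open, because the backcross mice carry Mus spretus alleles and the probes follow a reference sequence. That inherited alleles set the levels of these genes in both tissues remains a hypothesis.

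Endothelium, smooth muscle and matrix genes were lower in female dorsal skin, with a median of -0.37 over the 38 genes, although none of these lists passed camera with an estimated correlation. A smaller share of dermis in the female pieces would lower mast cell genes as well, but their median was 0.01 and their lowest member (-0.13) lay above the highest endothelium gene (-0.19), which speaks against it as the whole cause for endothelium, unless mast cells differ between the sexes themselves, as in tail skin (median 0.26). Dermal papilla (-0.13) and Schwann cell (-0.13) medians were lower and epidermal differentiation was higher (7 of 19 called), so a smaller share of dermis as part of the cause stays open. Random lists of other genes at the same level had medians of at least -0.064, which speaks against the scaling of the arrays, and within batch 1 10 of 12 endothelium genes were lower, which speaks against the sexes falling unequally on batches. A lower content of vessels and matrix in female dorsal skin, or lower expression per cell, stays open as a biological hypothesis and was not tested.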

How the results depend on the processing

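The alternatives that left out the 5 arrays least like their group or the 3 unusual tail arrays, used the skeletal muscle covariate, or correlated tissues only within dorsal batch 1 and tail batch 4 were chosen after seeing the data, and the others before.

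Of 108 alternative values of the counts that answer a comparison, 90 stayed within 1.5 times the reported count. With a size limit of 1.5 times in place of 2 times, the tail and dorsal comparison gave 3585 genes and the anagen comparison 281, because a lower limit admits more genes. With the mean of the skeletal muscle list as a covariate, the sexes in tail skin differed in 322 genes in place of 534, and the cause was not tested. With only genes above the median level, the batches differed in 1 gene in place of 2, with fewer genes tested.

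The number of lists past the test depended most on the correlation assumed between genes. Camera with an estimated correlation passed 21 of 264 lists in place of 115: 0 in the tail and dorsal comparison, 5 in the anagen comparison, 0 in the comparison of tails by the state of the dorsal skin, 4 in the difference between anagen effects, 3 and 4 for the sexes in dorsal and tail skin, 1 in the difference between sex effects and 4 between batches. Fry passed 31 in the tail and dorsal comparison, 1 in the comparison of tails, 7 in the difference between anagen effects, 7 for the sexes in tail skin and 3 between batches, and 85 in total. The smaller counts with an estimated correlation follow from its construction, since members that vary together count for less, and the cause of the shifts with fry was not tested.

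Among the alternative values of single genes, correlations and co-expression, 4452 kept their direction and side of the threshold, 44 were no longer past it, 53 were newly past it and 22 reversed. The only called value among these was Krt27, higher in tail skin by 4.37 but at -0.17 (adjusted p = 0.661) with anagen dorsal arrays in place of non-anagen ones. In that setting Krt25 fell to 0.93, Krt71 to 0.76 and Krt73 to 0.91, since anagen dorsal skin expresses the inner root sheath genes. Another 11 named genes lost the size limit of 2 times there and kept their direction: Dlx3 (0.82), Fgf18 (-0.91), Lgr6 (-0.61), Wif1 (0.84), Aurkb (0.92), Kif11 (0.77), Birc5 (0.71), Scd3 (-0.81), Cpa3 (0.66), Mcpt4 (0.60) and Ifit1 (-0.82). In all, 941 genes were called in place of 1123.

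The other 21 reversed values had not been called. Between tail and dorsal skin they were Blnk (-0.018) and Kdm5d (-0.021) after quantile normalization, Kdm5d with arrays shifted to the same median (-0.089), within batches 1 and 4 (-0.025) and with the skeletal muscle covariate (-0.02), Cox8b with that covariate (0.12), and Fn1 (-0.078) and Slc4a1 (-0.67) with anagen dorsal arrays in place of non-anagen ones. The others were Xist in the anagen comparison without sex as a covariate (0.38), Krt15 in the comparison of tails after quantile normalization (0.005), with the same median (0.027) and without the 5 arrays least like their group (0.069), and Tyr between the sexes in dorsal skin after quantile normalization (-0.008) and with the same median (-0.021). For the correlation between tissues they were Tyr within batches 1 and 4 (-0.002) and Xist without the 3 unusual tail arrays (-0.005). The co-expression difference reversed for smooth muscle (0.015) and Y-linked genes (-0.039) and for X genes expressed from both copies (-0.019) with rho, and for smooth muscle (0.015) and Y-linked genes (-0.097) without the 2 mice farthest in the list mean. Except where the alternative's own construction shows it, the cause was not tested.

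Of 1386 list medians under alternatives, 49 changed sign, among them the dermal extracellular matrix between tail and dorsal skin (0.11 to -0.03 with the same median) and skeletal muscle in 4 comparisons once its own mean was a covariate.

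Pairing changed little in the tail and dorsal comparison, which gave 1121 genes with mouse as a random block and 1129 with the difference within each mouse. The random block raised the count for the difference between sex effects from 1711 to 2043 genes. The correlation between tissues gave 281 to 442 genes over its alternatives, against 366.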

Other observations

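All tests in this part were chosen after the data were seen. The list means correlated here were not adjusted for sex or batch.

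The 14 anagen dorsal arrays ranged widely in hair genes. Their inner root sheath means ran from 6.26 to 11.39, with the highest non-anagen array at 6.40. The inner root sheath and hair shaft means rose together across these arrays (r = 0.970; rho = 0.969; permutation p = 1e-05 for both, the smallest possible; r = 0.963 without the 2 farthest; adjusted p = 4.7e-05 over 19 relations), and across 97 tails r was also 0.970 (rho = 0.969, permutation p = 1e-05; 0.970 within batch 4). The pigment mean followed the inner root sheath in anagen dorsal skin (r = 0.703, permutation p = 0.0032; rho = 0.811, permutation p = 0.00076; r = 0.587 without the 2 farthest; adjusted p = 0.0075) and not in tail skin (r = 0.039, permutation p = 0.71; rho = 0.013, permutation p = 0.9), and the difference between these was not tested. The mitotic mean did not follow it in anagen dorsal skin (r = 0.005, permutation p = 0.98; rho = 0.042, permutation p = 0.89) and followed it in tail skin (r = 0.339, permutation p = 0.00079; rho = 0.328, permutation p = 0.0012; r = 0.356 without the 2 farthest, 0.340 within batch 4; adjusted p = 0.0025), and this difference was not tested either. The white adipocyte mean also followed the inner root sheath in anagen dorsal skin (r = 0.646, rho = 0.626, adjusted p = 0.031) and in tail skin (r = 0.314, rho = 0.344, adjusted p = 0.0051). The stem cell mean followed it in tail skin (r = 0.544, rho = 0.557, adjusted p = 4.7e-05) and not in anagen dorsal skin (r = 0.346, rho = 0.305, adjusted p = 0.37). This difference between 97 tails and 14 anagen dorsal arrays was not tested either. Inner root sheath and white adipocyte genes leaned higher in female than in male tails, so sex may add to the relations in tail skin.

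Of 45 keratin-associated protein genes, 43 were called higher in tail skin (median 4.61) and 41 in anagen dorsal skin (median 2.91), each against non-anagen dorsal skin.

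The means of 7 lists in dorsal and tail skin of the same mouse were compared across mice, and none passed after adjustment over 19 relations, with r from -0.247 to 0.190.

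The 3 tail arrays that the labels place in batch 3 were not centred on the other tails (0.541 scaled units, with 75 of 100 random sets as small), unlike 3 male tail arrays labelled batch 4 (0.05). Dorsal batch 2 lay 0.27 units from the other dorsal arrays, below all of 100 random sets of 10 (lowest 0.327). In that batch Xist was at 13.36 in 3 females against 11.44 in 46 females of batch 1, and Eif2s3y was at 1.96 against 3.62.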
